A study of Homo sapiens with 12 samples.

How the data were processed

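Gene expression was measured by RNA sequencing in HMEC-1 cells of 4 groups with 3 libraries each, namely cells given a miR-126, miR-143 or miR-150 mimic or a scrambled RNA. The deposited table held TPM for 187626 transcripts in 12 columns with a library each, and each column summed to 1000000 TPM. The authors made the TPM with kallisto, which assigns reads to annotated transcripts without placing them on the genome, per the submitters' processing notes. Those notes also name FastQC, sleuth and the genome build GRCh38 (hg38); their versions, the transcript annotation and any filter are not given in the sources used here. TPM divide by transcript length and by the library's total, so a large change in a few abundant transcripts moves all others. A difference in RNA quality that depends on transcript length stays in the values, and the number of reads behind a value is lost. Depth per library is therefore unknown, and precision was judged from the spread between libraries alone.

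Columns were matched to samples by their names, which give the mimic and the replicate number, and 0 columns were left without a sample. TPM of transcripts were summed per gene symbol, which left out 171 transcripts without a gene and gave 36433 symbols. The 13750 genes with at least 1 TPM in at least 3 libraries were tested, on the scale log2(TPM + 1), which understates the change of genes with low values. Of the tested symbols, 677 cover more than 1 Ensembl gene. Gene positions, transcript lengths and 3' UTRs came from GENCODE release 29 on GRCh38, in which 169900 transcripts of the table (90.55%) were found by identifier.

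The design fixed before the data were examined named a count model for a table of estimated counts and limma for a table of TPM alone. The unit found was TPM, so limma was used, and comparisons with count models could not be made. A linear model with the group as its only term was fitted to all 12 libraries with limma 3.58.1 (moderated test with a mean-variance trend, two-sided), and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The median residual SD was 0.272 on the log2 scale. Each mimic was compared with the scrambled control and with each other mimic. On simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale among 13750, the fit recovered 71 and 95 for miR-126, 62 and 97 for miR-143, and 62 and 94 for miR-150 against the control, with 10, 13 and 6 false calls. Genes with low values were not among those changed. The simulated noise was independent, without the correlation between libraries or the bias by transcript length described below. Recovery and false calls in the real data may therefore differ.

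Replicate numbers 2 to 4 recur in every group, and the labels do not say what they mark. Residuals of same-numbered libraries correlated across genes with 0.29, 0.63 and 0.40 (numbers 2, 3 and 4) for miR-126 against the control, 0.32, 0.66 and 0.37 for miR-126 against miR-143, 0.29, 0.55 and 0.28 for miR-126 against miR-150, and 0.59, 0.63 and 0.74 for miR-143 against miR-150. All lie above 0.1, so for these comparisons a fit with the number as a block is given beside the result where it changes a test or the call of a named gene or moves a count of all genes by over 1.5 times, with the called members of the lists described there.

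A set of 26 gene lists was fixed before the data were examined, covering reported targets of the 3 microRNAs, VEGF and angiopoietin, NOTCH, and WNT and Norrin signalling, endothelial identity, leukocyte adhesion, interferon-stimulated genes, S phase, G2 and M phase, p53 targets, cholesterol synthesis, glycolysis, hypoxia, protein folding and amino acid stress, MAPK feedback and immediate early genes, TGF-beta and mesenchymal genes, extracellular matrix, integrins, microRNA machinery, markers of epithelium, fibroblasts and pericytes, leukocytes and lymphatic endothelium, and mitochondrially encoded mRNAs. Each list with at least 5 tested members was tested with camera in limma (correlation preset to 0.01, and estimated), adjusted over 75 tests against the control, and separately over the tests between mimics, which were added later. In fry, which asks whether a list's genes move on balance one way, 1 test passed. With the preset correlation, other splits of the libraries of a comparison also called lists, some of them more than the real split. A list that passed at the preset correlation alone is therefore weak evidence of a group difference.

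For seed sites, the 3' UTR of a gene was the longest of its protein-coding transcripts, available for 12425 tested genes. Genes with a match to bases 2 to 8 of the guide strand were set against genes without one in each library, and the 3 mimic libraries were compared with the other 9 by an exact permutation test over 220 splits (smallest p 0.0045) and with the 3 controls over 10 splits (smallest p 0.1), all two-sided. All 7-mers in at least 30 genes (16359) were also scanned, which recovered 50 of 50 7-mers whose genes were lowered by 0.1 in simulated data with independent noise. The simulated 7-mers were all more frequent than the miR-126-3p site (37 genes) and less frequent than the miR-150-5p site (3206 genes). Recovery of sites that rare or that common was not tested. Shares of sites among called genes were compared by Fisher's exact test with 95% intervals, and, after the data were seen, within strata of 3' UTR length holding equal numbers of genes by the Mantel-Haenszel method.

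Genes named in the text followed a rule fixed in advance. Per comparison with the control it took the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 TPM, all 3 mimic libraries on 1 side of all 3 controls, and a proper gene symbol. It added up to 6 reported targets with the smallest adjusted p, a fixed set for their own mimic whatever their p (among them SPRED1, PIK3R2, VCAM1, MAPK7, HK2, MYB, CXCR4, DLL4 and FZD4), up to 4 called genes per list, and the 6 largest falls among called genes with a seed site. Between mimics it took the 5 largest differences each way. Some genes that the rule picks are not reported here.

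Alternatives covered the pseudocount (0.1 TPM), filters, the replicate block, the 6 libraries compared alone, transcripts in place of genes, stricter thresholds and leaving out each library. Added after the data were seen were fits without the 2 libraries that favour short transcripts, with the trend on transcript length removed, with libraries centred on the median gene, quantile normalized or weighted by quality, with sums per Ensembl gene, and with the other mimics as the baseline. Computation used R 4.3.3 with the package data.table (1.17.8) and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.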

Results

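RNA was sequenced from HMEC-1, an immortalised line of human dermal microvascular endothelial cells, 48 h after transfection with 50 nM of a double-stranded microRNA mimic or of a scrambled RNA. A mimic supplies a cell with extra copies of a mature microRNA, a small RNA that lowers transcripts with matching sites. The 4 groups were miR-126, miR-143 and miR-150 mimics and the scrambled control, with 3 libraries each, numbered 2 to 4 in the labels. The study's title places these microRNAs in abnormal growth of retinal vessels, and each comparison asked which transcripts of endothelial cells differed when the level of the microRNA was raised. Values were TPM, abundances that share a constant total in each library, summed per gene symbol, and 13750 genes with at least 1 TPM in at least 3 libraries were tested. TPM hold no read totals, so the depth of each library is unknown and no interval that needs it is given. Between 12299 genes (miR-150 mimic replicate 4) and 13564 genes (miR-126 mimic replicate 3) reached 1 TPM. Libraries of a group correlated across genes with a Pearson r between 0.952 and 0.99 on the log2 scale. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

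The libraries of miR-143 mimic replicate 4 and miR-150 mimic replicate 4 stood apart from the other 10. The Spearman correlation across genes between a gene's deviation from its mean and its transcript length was -0.40 and -0.55 in them, and lay between -0.01 and 0.29 in the others. Transcripts of ribosomal proteins held 24.0% of TPM in miR-150 mimic replicate 4, and transcripts encoded by mitochondrial DNA 1.35%. In the other 11 libraries these shares were 13.5% to 17.9% and 2.07% to 2.83%. Each count of genes is therefore also given without these 2 libraries, an alternative chosen after the data were seen.

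**Figure D1:**
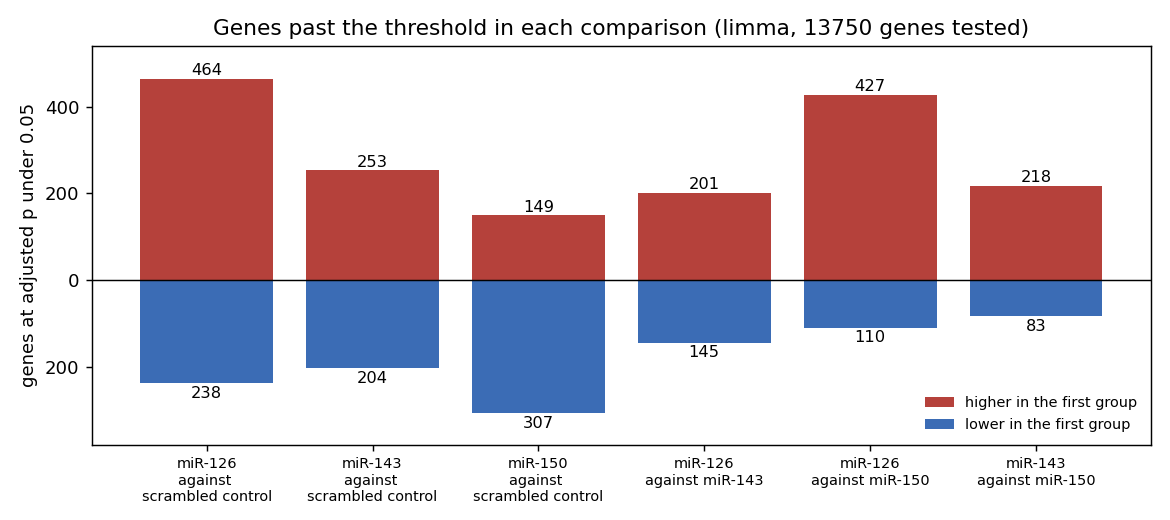
Number of genes at an adjusted p under 0.05 (limma) in each of the 6 comparisons, with genes higher in the group named first above 0 and genes lower in it under 0. The miR-126 mimic had 464 higher and 238 lower genes against the control, and the miR-150 mimic had 149 higher and 307 lower.

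With the miR-126 mimic, MMP14, COLGALT1 and ITGAV were among the 10 largest falls against scrambled RNA. MMP14, the membrane-anchored matrix metalloproteinase (chromosome 14, 22836557 to 22849027), measured 78.2 ± 11.4 TPM against 314 ± 11.8 TPM in the control (SD, n = 3 each). COLGALT1, which adds galactose to collagen (chromosome 19, 17555594 to 17583162), measured 47.5 ± 1.84 against 191 ± 15.8 TPM. ITGAV, the integrin alpha V subunit (chromosome 2, 186590065 to 186680901), measured 24.3 ± 1.99 against 100.1 ± 18.9 TPM. Their log2 fold changes were -2.001 (SE 0.165, adjusted p = 9.95e-05), -1.99 (SE 0.108, adjusted p = 5.73e-06) and -1.98 (SE 0.42, adjusted p = 0.0208) in limma's two-sided test. Among genes that rose, GPSM3, a modulator of G protein signalling (chromosome 6, 32190766 to 32195523), measured 33.9 ± 2.57 against 6.40 ± 0.191 TPM, and MNAT1, a subunit of the CDK-activating kinase (chromosome 14, 60734742 to 60969953), 85.7 ± 1.98 against 19.6 ± 1.24 TPM. GPSM3 overlaps NOTCH4 in the annotation, so the value of either is uncertain.

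The other genes among the 10 largest falls were PM20D2, the metalloprotease ADAM19, DCBLD2, SOWAHC, the insulin-like growth factor binding protein IGFBP5, the zinc transporter SLC39A6 and the lipid phosphatase SGPP1, with log2 fold changes from -2.15 (PM20D2) to -1.81 (SGPP1). The 10 largest rises also held IRF7, the interferon-regulating transcription factor, with C3orf52, the membrane fusion ATPase NSF, RARRES3, HIPK1, MARCKSL1, the chaperone CANX and CACUL1, from 2.16 (IRF7) to 1.68 (CACUL1). GPSM3, MNAT1, C3orf52, NSF, HIPK1, CANX and CACUL1 hold in their 3' UTR the 7-mer GGTTGTG. This 7-mer was singled out in a scan of these same libraries as the lowest in the controls, so a test on them restates that choice. With UTR and transcript features removed, its carriers were lower in the controls than in the mimic libraries (log2 difference -0.209, exact permutation p = 0.0045). Without that step the difference was -0.135 (exact permutation p = 0.05), and miR-150 mimic replicate 4 lay under all 3 controls. IRF7, HIPK1, ITGAV and SGPP1 missed the threshold in 5 of 6 fits that left out 1 library, whereas MMP14, ADAM19, COLGALT1, GPSM3 and MNAT1 passed it in every such fit.

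By fixed gene lists, 3 of 32 tested genes of extracellular matrix and proteases fell with the miR-126 mimic and 0 rose (3 and 0 adjusted over the list alone). The list as a whole lay lower than other genes (camera adjusted p = 9.1e-08; adjusted p = 0.79 with an estimated correlation). These were MMP14, the plasminogen activator PLAT (log2 fold change -0.79) and fibrillin FBN1 (-1.17). Of 25 genes of TGF-beta signalling and the mesenchymal state, 6 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 6.7e-05; adjusted p = 0.78 with an estimated correlation), with TGFBI at -0.998, the transcription factor SNAI1 at -1.03 and vimentin (VIM) at -0.55 among those that fell. Among 27 integrin and focal adhesion genes, 4 fell and 0 rose (6 and 0 adjusted over the list alone; camera adjusted p = 8.5e-05; adjusted p = 0.99 with an estimated correlation): the integrin-linked kinase ILK (-1.32), ITGAV, RHOA (-0.50) and ITGA3 (-0.54). ILK overlaps TAF10, and its value is uncertain for that reason; FBN1 and ITGA3 missed the threshold in all 6 fits that left out 1 library, RHOA in 5 and NOS3, named next, in 4. Endothelial identity genes lay lower (camera adjusted p = 0.003; adjusted p = 0.99 with an estimated correlation), with NOS3, the endothelial nitric oxide synthase, the 1 gene of 24 that fell (-0.62; 3 adjusted over the list alone). Targets of p53 lay higher (camera adjusted p = 0.019; adjusted p = 0.99 with an estimated correlation), and DDB2, a DNA repair gene, was the 1 of 22 that rose (0.70; 4 adjusted over the list alone). With the replicate block, 0 rose and 14 fell among matrix genes, 5 and 11 among TGF-beta genes, 0 and 8 among integrin genes, 2 and 7 among endothelial genes and 13 and 0 among p53 targets. Markers of fibroblasts and pericytes, cells that also make matrix, summed to 68.85, 31.71 and 75.51 TPM in miR-126 mimic replicates 2, 3 and 4 and to 116.5, 32.2 and 138 TPM in the controls, and did not pass the test (camera adjusted p = 0.85).

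Interferon-stimulated genes were higher with the miR-126 mimic in all 34 tested members, with a median log2 fold change of 2.10 (camera adjusted p = 4.9e-07; adjusted p = 0.99 with an estimated correlation). IRF7 was the 1 member past the threshold by itself (2 adjusted over the list alone). The list's level varied between replicate numbers in every group: its mean log2 value was 3.24, 5.24 and 3.13 in control replicates 2, 3 and 4, and 5.41, 7.41 and 4.93 in the miR-126 mimic libraries. Each miR-126 mimic library thus exceeded the control library of its own number, by 2.17, 2.16 and 1.80. With the replicate number as a block, 33 of the 34 genes passed the threshold, and the list passed with an estimated correlation too (adjusted p = 0.034 with an estimated correlation).

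Of 22 reported miR-126 targets, 2 fell and 1 rose (7 and 1 adjusted over the list alone), and the list lay lower (camera adjusted p = 0.00073; adjusted p = 0.99 with an estimated correlation). GOLPH3, a Golgi protein, and ADAM9, a metalloprotease, had log2 fold changes of -1.13 (SE 0.128) and -1.57 (SE 0.227), and the homeobox gene HOXA9 had 0.94 (SE 0.173). The inhibitors PIK3R2 (-0.95, adjusted p = 0.0566) and SPRED1 (-0.61, adjusted p = 0.441), EGFL7, whose intron encodes miR-126 (-0.86, adjusted p = 0.0703), and CRK (-0.55, adjusted p = 0.0865) did not pass. With the replicate block PIK3R2, EGFL7 and CRK did (adjusted p = 0.00703, 0.00459 and 0.0205), and 9 of the 22 fell and 3 rose. VCAM1 lay under the filter, at 0.260 ± 0.108 TPM against 0.489 ± 0.121 TPM. Reported miR-143 targets also lay lower (0 higher and 3 lower of 20, 0 and 3 adjusted over the list alone, 1 and 4 with the replicate block; camera adjusted p = 0.026; adjusted p = 0.99 with an estimated correlation). So did the 13 mitochondrially encoded mRNAs, of which 0 passed by themselves and 0 adjusted over the list alone (camera adjusted p = 0.044; adjusted p = 0.99 with an estimated correlation). Both lists missed the threshold with the trend on transcript length removed (adjusted p = 0.072 and 0.11).

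The other lists did not pass in this comparison. By member, 2 rose in VEGF and angiopoietin signalling (the angiogenic peptide apelin, APLN, 1.24, and ESM1, 1.03), 2 in glycolysis (PFKL and PFKFB4) and 2 among immediate early genes (FOSB and FOS), and 1 rose in NOTCH signalling (NOTCH4). CTNNB1 (WNT and Norrin signalling), CCL2 (leukocyte adhesion), FEN1 (S phase), XBP1 (protein folding stress) and PDPN (lymphatic markers) were each the 1 gene that fell in their list. NOTCH4, CTNNB1, CCL2 and FEN1 missed the threshold in 5 of 6 fits that left out 1 library. With the replicate block, WNT and Norrin genes passed toward lower values (adjusted p = 0.034; adjusted p = 0.84 with an estimated correlation and the block) and S phase genes toward higher ones (adjusted p = 0.011; also 0.84).

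In all, 702 genes passed the threshold in the miR-126 mimic, 464 higher and 238 lower, of which 147 and 91 differed by at least 1 on the log2 scale. The 3 mimic libraries lay all above or all under the 3 controls for 34.1% of genes, against 10% by chance, and the median log2 fold change of all genes was 0.10. Centring each library on its median gene gave 432 higher and 483 lower, and quantile normalization 482 and 547, both chosen after the data were seen. With the replicate number as a block the counts were 1629 and 702, and without the 2 libraries that favour short transcripts 1211 and 624. The count was 225, 357 and 250 without miR-126 mimic replicates 2, 3 and 4, and 250 and 214 without control replicates 2 and 4.

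**Figure D2:**
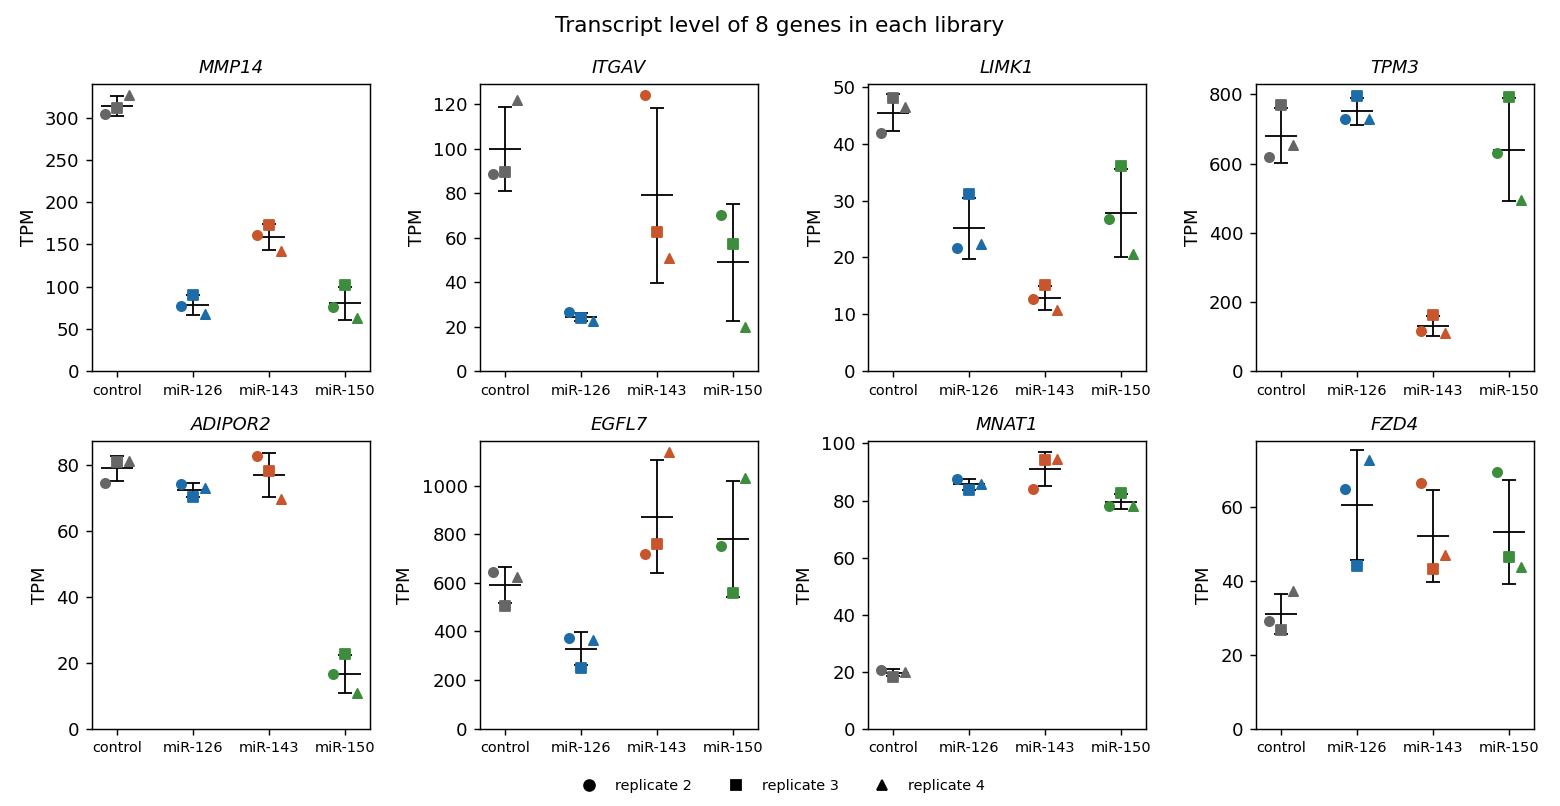
TPM of 8 genes in each of the 12 libraries, where the long bar is the group mean, the whiskers are 1 SD (n = 3) and the symbols give the replicate number. MMP14 was 314 TPM in the control and 78.2, 159 and 80.0 TPM with the miR-126, miR-143 and miR-150 mimics; TPM3 was 129 TPM with the miR-143 mimic against 681 TPM in the control, and ADIPOR2 16.6 TPM with the miR-150 mimic against 78.9 TPM.

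With the miR-143 mimic, GXYLT1, TPM3 and LIMK1 were among the 10 largest falls against scrambled RNA. TPM3, a tropomyosin that binds actin filaments (chromosome 1, 154155304 to 154194648), measured 129 ± 28.8 TPM against 681 ± 79.2 TPM in the control (SD, n = 3 each), a log2 fold change of -2.40 (SE 0.182, adjusted p = 0.000133). LIMK1, the kinase that inactivates cofilin (chromosome 7, 74082933 to 74122525), measured 12.9 ± 2.16 against 45.5 ± 3.20 TPM (log2 fold change -1.75, SE 0.211). GXYLT1, a xylosyltransferase that acts on NOTCH, had the largest fall, from 48.9 ± 4.94 to 8.29 ± 2.69 TPM (-2.46, SE 0.313). Among genes that rose were S1PR1, the endothelial receptor for sphingosine-1-phosphate (152 ± 17.7 against 50.3 ± 5.20 TPM), and EDNRB, the endothelin receptor B (16.0 ± 4.85 against 4.53 ± 0.171 TPM).

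Other large falls were in the zinc transporter SLC39A10, the homeobox gene PRRX1, ADAMTS18, the adenylate kinase AK5, the kinase HIPK2 and TAF10, with log2 fold changes from -2.03 (SLC39A10) to -1.77 (TAF10, which overlaps ILK and is uncertain for that reason). The other large rises were MNAT1 (2.16), the kinase UHMK1, SULT1A4, C3orf52, the complex I subunit NDUFB5, the neutrophil chemokine CXCL5, CANX and SNU13 (1.54). SULT1A4 has a near-identical copy and is uncertain. MNAT1, UHMK1, SULT1A4, C3orf52, CXCL5, S1PR1, CANX and SNU13 hold the 7-mer GGTTGTG in the 3' UTR. EDNRB missed the threshold in 4 of 6 fits that left out 1 library, UHMK1 and SULT1A4 in 5 and HIPK2 in all 6, while TPM3, LIMK1, GXYLT1 and S1PR1 passed in every such fit.

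Of 20 reported miR-143 targets, 6 fell and 0 rose (7 and 0 adjusted over the list alone), and 0 had a log2 fold change above 0 (camera adjusted p = 2.1e-08; adjusted p = 0.79 with an estimated correlation). Among those that fell were LIMK1, ASAP3 (-1.14), the actin-bundling protein fascin (FSCN1, -0.67), IGFBP5 (-1.34) and the glycolytic enzyme hexokinase 2 (HK2, -1.34, adjusted p = 0.0444). MAPK7 (-0.50, adjusted p = 0.201) did not pass. IGFBP5 missed the threshold in all 6 fits that left out 1 library, HK2 and FSCN1 in 5 and ASAP3 in 4. Reported miR-150 targets also lay lower (0 higher and 2 lower of 18, 1 and 4 adjusted over the list alone; camera adjusted p = 0.005; adjusted p = 0.99 with an estimated correlation), with MMP14 at -0.98 and ADAM19 at -0.98, the latter lost in 5 of 6 such fits. The mean log2 level of the miR-150 targets differed from the control of the same number by -0.054, -0.323 and -0.719 in replicates 2, 3 and 4. Replicate 4 favours short transcripts.

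Genes of leukocyte adhesion and chemokines lay higher with the miR-143 mimic (camera adjusted p = 0.0015; adjusted p = 0.99 with an estimated correlation), and NFKBIA, the inhibitor of NF-kappa-B, was the 1 of 16 that rose (0.71; 1 adjusted over the list alone). Interferon-stimulated genes lay higher in 33 of 34 members, with a median log2 fold change of 1.20 (camera adjusted p = 4.5e-05; adjusted p = 0.99 with an estimated correlation). In limma 0 of them passed alone, also adjusted over the list alone, and their mean log2 level was 4.45, 6.54 and 4.14 in replicates 2, 3 and 4. With the replicate block, 23 of the 34 passed and the list passed with an estimated correlation too (adjusted p = 0.034), although the numbers pair these libraries less clearly. TGF-beta and mesenchymal genes lay lower (0 higher and 2 lower of 25, and 0 and 2 adjusted over the list alone; camera adjusted p = 0.019; adjusted p = 0.80 with an estimated correlation). Matrix genes and proteases lay lower too (0 higher and 4 lower of 32, 0 and 5 adjusted over the list alone; camera adjusted p = 0.044; adjusted p = 0.99 with an estimated correlation). The matrix genes that fell were MMP14, thrombospondin THBS1 (-1.58), the urokinase PLAU (-0.87) and TIMP3 (-0.90), and this list missed the threshold without the 2 libraries that favour short transcripts (adjusted p = 0.058) and with the trend on transcript length removed (adjusted p = 0.34). THBS1 missed it in 4 of 6 fits that left out 1 library, and PLAU and TIMP3 in 5. The fibroblast and pericyte markers summed to 60.44, 28.43 and 60.02 TPM in miR-143 mimic replicates 2, 3 and 4, against the same controls, and did not pass (camera adjusted p = 0.48).

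The miR-143 mimic had 457 genes past the threshold, 253 higher and 204 lower, with 71 and 76 at an absolute log2 fold change of at least 1. Groups did not overlap for 25.3% of genes (10% by chance), and the median log2 fold change of all genes was -0.04. Without the 2 libraries that favour short transcripts, 395 were higher and 312 lower. The count was 235, 232 and 182 without miR-143 mimic replicates 2, 3 and 4, and 155 and 139 without control replicates 2 and 4.

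With the miR-150 mimic, ADIPOR2, MMP14 and PLOD2 were among the 10 largest falls against scrambled RNA. ADIPOR2, an adiponectin receptor (chromosome 12, 1688574 to 1788678), measured 16.6 ± 5.83 TPM against 78.9 ± 3.84 TPM in the control (SD, n = 3 each), a log2 fold change of -2.23 (SE 0.197, adjusted p = 0.000293). MMP14 measured 80.0 ± 19.5 against 314 ± 11.8 TPM (-1.99, SE 0.165, adjusted p = 0.000269). PLOD2, the lysyl hydroxylase that prepares collagen for cross-linking (chromosome 3, 146069440 to 146163653), measured 91.1 ± 26.8 against 307 ± 29.03 TPM (-1.78, SE 0.218, adjusted p = 0.00111). Among genes that rose, carbonic anhydrase CA2 (chromosome 8, 85463852 to 85481493) measured 15.5 ± 1.18 against 3.32 ± 0.792 TPM (1.94, SE 0.239, adjusted p = 0.00117).

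KCTD20, LRRC17, the chromatin remodelling subunit SMARCD2, ADAM19, the thrombin receptor F2R, MPZL1 and the matrix protein LTBP2 completed the 10 largest falls, from -2.06 (KCTD20) to -1.78 (LTBP2). The remaining large rises were MNAT1 (1.97), GPSM3, the sulfotransferase CHST14, NDUFB5, NARS2, SNU13, TSPAN1, MARCKSL1 and the ceramide glucosyltransferase UGCG (1.42). MNAT1, GPSM3, CHST14, NARS2, SNU13 and UGCG hold the 7-mer GGTTGTG in the 3' UTR. UGCG and F2R missed the threshold in 4 of 6 fits that left out 1 library; ADIPOR2, MMP14, PLOD2 and CA2 passed in every such fit.

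Of 18 reported miR-150 targets, MMP14 and ADAM19 (-1.92) fell and 0 rose (3 and 1 adjusted over the list alone), and 1 had a log2 fold change above 0 (camera adjusted p = 0.001; adjusted p = 0.99 with an estimated correlation). The glucose transporter SLC2A1 (-0.61, adjusted p = 0.0919), NOTCH3 (-0.73, adjusted p = 0.233), EP300 (-1.15, adjusted p = 0.257), the chemokine receptor CXCR4 (-0.38, adjusted p = 0.43) and the NOTCH ligand DLL4 (-0.45, adjusted p = 0.678) did not pass. Single libraries weighed on both EP300 and DLL4: EP300 measured 19.85, 14.3 and 3.231 TPM in miR-150 mimic replicates 2, 3 and 4, and DLL4 0.6772, 5.181 and 7.769 TPM against 4.984 to 5.204 TPM in the controls. FZD4, the receptor for Norrin in retinal vessels, measured 53.3 ± 14.1 against 31.1 ± 5.43 TPM (0.74, adjusted p = 0.127), and MYB lay under the filter, at 0.202 ± 0.0460 against 0.908 ± 0.586 TPM. FZD4 lay at a similar level with the miR-126 (60.6 ± 14.8 TPM) and miR-143 (52.3 ± 12.5 TPM) mimics.

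TGF-beta and mesenchymal genes lay lower with the miR-150 mimic (0 higher and 4 lower of 25, 0 and 10 adjusted over the list alone; camera adjusted p = 0.0015; adjusted p = 0.79 with an estimated correlation), among them TGFBI (-1.03), fibronectin FN1 (-0.67) and N-cadherin CDH2 (-1.58). Matrix genes and proteases lay lower too (0 higher and 3 lower of 32, 0 and 6 adjusted over the list alone; camera adjusted p = 0.001; adjusted p = 0.99 with an estimated correlation), namely MMP14, SPARC (-0.67) and PLAU (-0.81). CDH2 and PLAU missed the threshold in 5 of 6 fits that left out 1 library, and SPARC in 4. Integrin and focal adhesion genes had the same direction (camera adjusted p = 0.004; adjusted p = 0.99 with an estimated correlation), with 0 of 27 past the threshold and 0 higher and 3 lower adjusted over the list alone. Their mean log2 level differed from the control of the same number by -0.093, -0.21 and -0.926 in replicates 2, 3 and 4. Replicate 4, which favours short transcripts, thus weighed most. The 13 mitochondrially encoded mRNAs lay lower (median log2 fold change -0.41, 0 past the threshold and 0 adjusted over the list alone; camera adjusted p = 0.011; adjusted p = 0.99 with an estimated correlation), and missed the threshold without the 2 libraries that favour short transcripts (adjusted p = 0.098). The fibroblast and pericyte markers summed to 48.3, 29.1 and 38.7 TPM in miR-150 mimic replicates 2, 3 and 4 and to 116.5, 32.2 and 138 TPM in the controls, and did not pass the test (camera adjusted p = 0.22).

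The miR-150 mimic had 456 genes past the threshold, 149 higher and 307 lower, with 47 and 118 at an absolute log2 fold change of at least 1. Groups did not overlap for 21.5% of genes (10% by chance), and the median log2 fold change of all genes was -0.11; quantile normalization gave 301 higher and 372 lower. Without the 2 libraries that favour short transcripts, 282 were higher and 305 lower. The count was 280 without miR-150 mimic replicate 2, and 175, 294 and 125 without control replicates 2, 3 and 4.

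**Figure D3:**
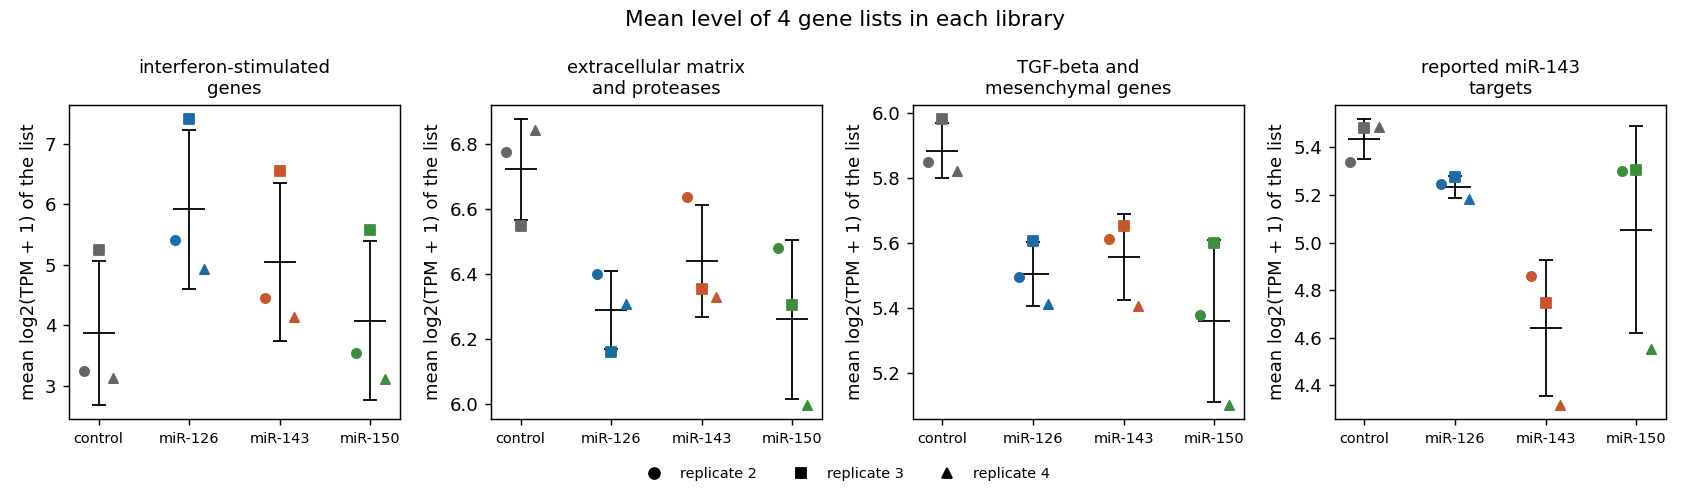
Mean log2(TPM + 1) of 4 fixed gene lists in each library, with group means and 1 SD (n = 3) and symbols for the replicate number. Interferon-stimulated genes lay at 5.41, 7.41 and 4.93 with the miR-126 mimic against 3.24, 5.24 and 3.13 in the control, and replicate 3 was the highest of its group in each group.

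Genes with a site for the guide strand of the mimic in their 3' UTR (a match to bases 2 to 8 of the microRNA) were lower in the libraries of the miR-126 and miR-143 mimics, while the difference for miR-150 missed the threshold. For miR-143-3p, 1794 genes with the site TCATCTC lay lower relative to other genes by a log2 difference of -0.16 in the 3 miR-143 mimic libraries against the other 9 (exact permutation p = 0.0182, two-sided, 220 splits). The 37 genes with the miR-126-3p site CGGTACG lay at -0.19 in the miR-126 mimic libraries (exact permutation p = 0.0045, the smallest that 220 splits can give). The 3206 genes with the miR-150-5p site TTGGGAG lay at -0.10 in the miR-150 mimic libraries, which did not pass (exact permutation p = 0.0545), while the 735 with the 8-mer TTGGGAGA lay at -0.20 (exact permutation p = 0.0136). With the replicate block the difference for TTGGGAG passed (-0.10, exact permutation p = 0.0409). Against the 3 controls alone the differences were -0.25, -0.19 and -0.12 for miR-126, miR-143 and miR-150, each with an exact permutation p of 0.1, the smallest that 3 against 3 can give. Without miR-143 mimic replicate 4, the miR-143 difference was -0.11 (exact permutation p = 0.0727), and without miR-150 mimic replicate 4 the miR-150 difference was -0.03 (exact permutation p = 0.4727); without miR-150 mimic replicate 3 it was -0.13 (exact permutation p = 0.0364). Both libraries lay low for sites of either microRNA, and without the pair the differences were -0.135 for miR-143 (exact permutation p = 0.0222) and -0.046 for miR-150 (exact permutation p = 0.0444). Tested as sets, all 3 lay lower (camera adjusted p = 0.0035 for miR-126, 1.3e-05 for miR-143 and 0.0035 for miR-150; adjusted p = 0.57 with an estimated correlation for each).

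Among the 199 genes that fell with the miR-143 mimic and have an annotated 3' UTR, 85 (42.7%) held a miR-143-3p site, against 14.0% of the other genes (odds ratio 4.59, 95% interval 3.41 to 6.16, Fisher's exact test p = 1.7e-22, two-sided). Among 252 that rose, 26 (10.3%) did. TPM3 holds the 8-mer TCATCTCA at chromosome 1, 154156791 to 154156798, and LIMK1 at chromosome 7, 74122125 to 74122132, both in the 3' UTR. Of 301 genes that fell with the miR-150 mimic, 143 (47.5%) held a miR-150-5p site, against 25.3% of the others (odds ratio 2.68, 2.11 to 3.39, Fisher's exact test p = 2.7e-16). Among 148 that rose, 15 (10.1%) did (odds ratio 0.321, 0.175 to 0.55, Fisher's exact test p = 2.7e-06). Genes with long 3' UTRs hold more sites, so the shares were also compared within strata of 3' UTR length (Mantel-Haenszel), after the data were seen. For the genes that fell the odds ratio was then 5.41 for miR-143 (95% interval 3.95 to 7.41) and 2.75 for miR-150 (2.14 to 3.53). For those that rose it was 0.918 (0.596 to 1.41) and 0.416 (0.232 to 0.746). ADIPOR2 holds 4 such sites in its 3' UTR, among them an 8-mer at chromosome 12, 1786280 to 1786287. MMP14 holds 2, at chromosome 14, 22846606 to 22846612 and 22847420 to 22847427, and KCTD20, SMARCD2, ADAM19 and F2R hold at least 1. Against the mean of the other mimics, ADIPOR2, KCTD20 and SMARCD2 were lower with the miR-150 mimic past the threshold of limma (-2.15, -1.89 and -1.79). MMP14 (-0.49), ADAM19 (-0.43) and F2R (-1.08) did not pass there (limma adjusted p = 0.0899, 0.247 and 0.101). Of 232 that fell with the miR-126 mimic, 3 (1.29%) held the rare miR-126-3p site, against 0.279% of the others (odds ratio 4.68, 0.914 to 15.1, Fisher's exact test p = 0.031). They were the phosphomannomutase PMM1 (-1.17, site CGGTACGA at chromosome 22, 41577001 to 41577008) and F8A1 and F8A3, near-identical copies whose values are uncertain and which missed the threshold in 5 of 6 fits that left out 1 library. Fisher's test counted these copies as 2 genes, although both hold the site at position 481 of their 3' UTR. Its p for miR-126 thus counts 1 sequence more than once, and its interval includes 1.

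**Figure D4:**
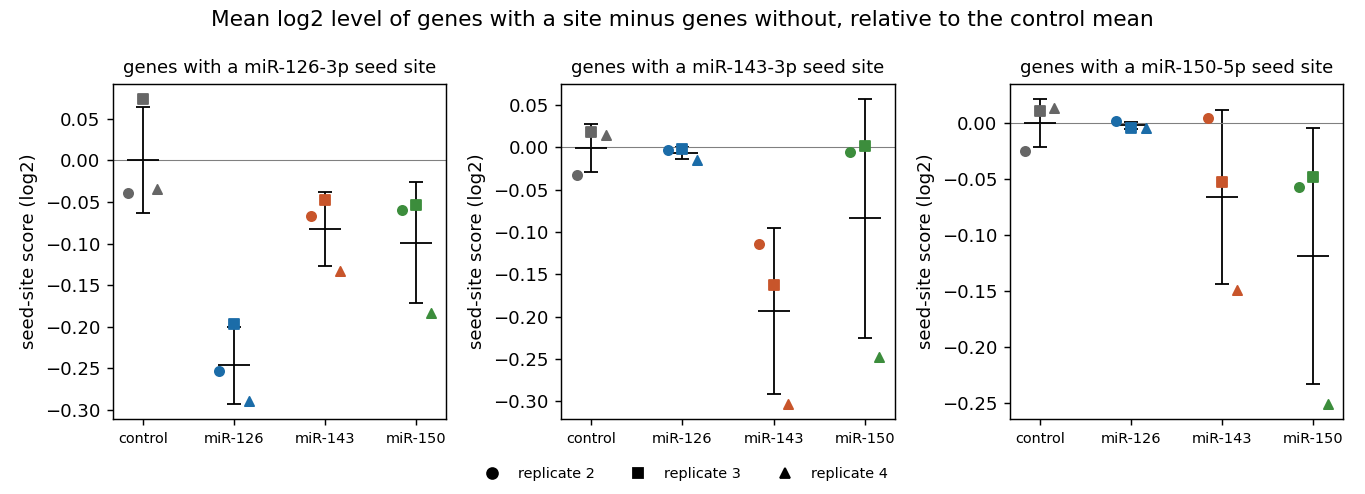
Seed-site score of each library, the mean log2 level of genes with a site minus that of genes without, relative to the mean of the controls, for the sites of miR-126-3p (37 genes), miR-143-3p (1794) and miR-150-5p (3206), with group means and 1 SD (n = 3). The miR-126 mimic libraries lie lowest in the first panel, while replicate 4 of the miR-143 and miR-150 mimics lies lowest in the others, at -0.30 and -0.25 for miR-143-3p sites and -0.15 and -0.25 for miR-150-5p sites.

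Between the mimics, the miR-126 mimic differed from the miR-143 mimic most in TPM3 (751 ± 39.6 against 129 ± 28.8 TPM, SD, n = 3 each) and GXYLT1 (41.6 ± 5.23 against 8.29 ± 2.69 TPM), with log2 differences of 2.55 (SE 0.182) and 2.23 (SE 0.313). KRT80, PTBP3 and the amino acid transporter SLC36A1 were higher as well, by 2.17, 2.02 and 1.85. Lower with the miR-126 mimic were PI16, SOWAHC, SLC39A6, the tetraspanin CD9 and SGPP1, and CD9 measured 379 ± 59.5 against 1239 ± 174 TPM (-1.71, SE 0.138); PI16 and SGPP1 missed the threshold in all 6 fits that left out 1 library, and PTBP3 and SLC36A1 in 5. EGFL7 was lower than with the miR-143 mimic (-1.39) and than with the miR-150 mimic (-1.22), past the threshold in both. Reported miR-143 targets lay higher than with the miR-143 mimic (5 of 20 past the threshold, 8 adjusted over the list alone, 10 with the replicate block; camera adjusted p = 0.00068; adjusted p = 0.89 with an estimated correlation). Reported miR-126 targets lay lower (1 higher and 3 lower of 22, 1 and 3 adjusted over the list alone, 5 and 3 with the replicate block; camera adjusted p = 0.0012; adjusted p = 0.89 with an estimated correlation). Interferon-stimulated genes had a median log2 difference of 0.81 and did not pass (camera adjusted p = 0.24), but passed with the replicate number as a block (20 of 34 past the threshold, against 0 without it; adjusted p = 1.4e-10; adjusted p = 0.15 with an estimated correlation and the block). Lists of endothelial identity, leukocyte adhesion, G2 and M phase, cholesterol synthesis, matrix, integrins and mitochondrially encoded mRNAs also lay lower (camera adjusted p = 0.00068, 0.0097, 0.041, 0.00027, 0.00061, 0.00039 and 0.031), and p53 targets and immediate early genes higher (0.0064 and 0.004). Each had at most 2 members past the threshold and an adjusted p of 0.89 with an estimated correlation. With the trend on transcript length removed, the leukocyte and mitochondrial lists missed the threshold (adjusted p = 0.12 and 0.23). The limma test gave 346 genes, 201 higher and 145 lower, with a median over all genes of 0.15 and non-overlapping groups for 25.4% (10% by chance). Centring gave 173 and 245, quantile normalization 210 and 282, the replicate block 1041 and 474, and the fit without the 2 libraries that favour short transcripts 325 and 253. Leaving out miR-126 mimic replicate 2, 3 or 4 gave 77, 183 and 88 genes, and miR-143 mimic replicate 2, 3 or 4 gave 160, 148 and 112.

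Against the miR-150 mimic, the miR-126 mimic had higher ADIPOR2 (72.5 ± 2.10 against 16.6 ± 5.83 TPM, log2 difference 2.11, SE 0.197) and FAM3C, a secreted cytokine-like protein (75.7 ± 10.9 against 17.7 ± 4.40 TPM, 2.05, SE 0.182). KCTD20, the calcineurin inhibitor RCAN1 and SMARCD2 were higher by 2.00, 1.96 and 1.93. IGFBP5 (-2.12), PM20D2, thrombomodulin THBD (-1.76), CD9 and CA2 were lower. Interferon-stimulated genes lay higher in all 34 members, with a median of 1.86 (0 past the threshold, 0 adjusted over the list alone and 32 with the replicate block; camera adjusted p = 0.00068; adjusted p = 0.89 with an estimated correlation). Reported miR-126 targets lay lower (0 higher and 4 lower of 22, 2 and 6 adjusted over the list alone, 3 and 6 with the replicate block; camera adjusted p = 3e-05; adjusted p = 0.89 with an estimated correlation). Endothelial identity, G2 and M phase, cholesterol synthesis and matrix lists lay lower (camera adjusted p = 0.008, 0.0011, 0.017 and 0.041) and p53 targets higher (0.041), with at most 3 members past the threshold and an adjusted p of 0.89 with an estimated correlation in each. Without the 2 libraries that favour short transcripts, the endothelial, cholesterol and p53 lists missed the threshold (adjusted p = 0.079, 0.29 and 0.11). In total 537 genes passed, 427 higher and 110 lower, with a median over all genes of 0.22 and non-overlapping groups for 25.9% (10% by chance). Centring gave 259 and 288, quantile normalization 283 and 330, the replicate block 2178 and 421, and the fit without the 2 libraries that favour short transcripts 435 and 261. The count was 117, 304 and 133 without miR-126 mimic replicates 2, 3 and 4, and 282 without miR-150 mimic replicate 2.

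The miR-143 mimic exceeded the miR-150 mimic in FAM3C (96.8 ± 14.7 against 17.7 ± 4.40 TPM, log2 difference 2.40, SE 0.182), ADIPOR2, the cortisone reductase HSD11B1, EDNRB and HNRNPH2. It lay under the miR-150 mimic in CA2 (2.13 ± 0.737 against 15.5 ± 1.18 TPM, -2.42, SE 0.239), TPM3, TAF10, GXYLT1 and IGFBP5. Reported miR-143 targets lay lower with the miR-143 mimic (0 higher and 2 lower of 20, 0 and 5 adjusted over the list alone, 1 and 7 with the replicate block; camera adjusted p = 4.6e-05; adjusted p = 0.89 with an estimated correlation). Interferon-stimulated genes lay higher in all 34 members, with a median of 0.92 (0 past the threshold, 0 adjusted over the list alone and 20 with the replicate block; camera adjusted p = 0.013; adjusted p = 0.89 with an estimated correlation). The mitochondrially encoded mRNAs lay higher in all 13 members (camera adjusted p = 0.0073). The lists of leukocyte adhesion (0.017) and integrins (0.022) also lay higher, and that of immediate early genes lower (0.048). Each had at most 1 member past the threshold and an adjusted p of 0.89 with an estimated correlation. Without the 2 libraries that favour short transcripts, the mitochondrial, integrin and immediate early lists missed the threshold (adjusted p = 0.26, 0.092 and 0.06). Here 301 genes passed, 218 higher and 83 lower, with non-overlapping groups for 15.1% (10% by chance) and a median over all genes of 0.07; quantile normalization gave 238 and 167. The replicate block gave 971 and 369, and the fit without the 2 libraries that favour short transcripts 154 and 108. The count was 127, 187 and 127 without miR-143 mimic replicates 2, 3 and 4, and 145 without miR-150 mimic replicate 2.

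Many of the genes called against the control were called in more than 1 mimic. MNAT1, NDUFB5 and the glycolytic enzyme PFKL rose with all 3 mimics, as did the angiogenic peptide apelin (APLN) and the tip cell proteoglycan ESM1, and MMP14, ADAM19, TGFBI and podoplanin (PDPN) fell with all 3; with the miR-143 mimic, ADAM19 missed the threshold in 5 and ESM1 in 4 of 6 fits that left out 1 library. In total 86 genes were higher and 26 lower with all 3 mimics. The miR-126 and miR-143 mimics shared 170 higher and 47 lower genes (8.54 and 3.53 for independent lists), miR-126 and miR-150 shared 107 and 52 (5.03 and 5.31), and miR-143 and miR-150 shared 97 and 44 (2.74 and 4.55). Lists against the same controls are not independent, so these expectations are too low. Groups without a change were simulated against the same controls, with libraries of a replicate number correlated as their residuals were, which was added after the data were seen. Across genes, the covariance of log2 fold changes was 0.0961, 0.0853 and 0.0926 for these pairs, against 0.0283, 0.0269 and 0.0439 in the simulation. The Pearson r of 0.58, 0.527 and 0.611 did not show an excess over it (0.569, 0.527 and 0.763). Simulated genes were independent of each other, so the spread between simulated sets is understated. With 3 controls they could not be split between comparisons, so part of the shared calls may come from the shared controls. The 7-mer GGTTGTG, singled out after the data were seen, stood in the 3' UTR of 27.4%, 33.7% and 38.5% of the genes higher with the miR-126, miR-143 and miR-150 mimics, against 10.3% of all 12425 genes with a 3' UTR. MNAT1 and PFKL hold this 7-mer, and NDUFB5, APLN and ESM1 do not.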

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

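The differences between mimics given here were planned tests, while the search for genes called in opposite directions against the control was applied after the results were seen. A total of 9 differences met it, each past the threshold of limma against the control in both mimics, with opposite signs, and past it between the mimics. Opposite calls against the same controls add up to a larger difference between the mimics. Passing between the mimics thus followed almost wholly from the search, and the adjusted p given for it here is no separate support. FAM3C, a secreted cytokine-like protein, was higher with the miR-126 mimic (0.77) and with the miR-143 mimic (1.12) and lower with the miR-150 mimic (-1.28), differences of 2.05 (adjusted p = 0.000368) and 2.40 (adjusted p = 0.000142). FAM3C2, a near-identical copy of FAM3C and uncertain for that reason, differed between the miR-126 and miR-150 mimics by 2.27 (1.17 against -1.095, adjusted p = 0.0005). MTCH2, a protein of the mitochondrial outer membrane, differed from the miR-150 mimic by 0.80 with the miR-126 mimic (adjusted p = 0.00127) and by 0.86 with the miR-143 mimic (adjusted p = 0.00103). SMIM3 differed by 1.55 between the miR-126 and miR-150 mimics (0.73 against -0.81, adjusted p = 0.00127). HSD11B1, which makes cortisol from cortisone, differed by 2.05 between the miR-143 and miR-150 mimics (0.98 against -1.07, adjusted p = 0.00117), and the potassium channel KCNK6 by 1.21 (0.60 against -0.61, adjusted p = 0.00168). HSD11B1 was low, at 1.942, 1.975 and 2.618 TPM in the controls and 0.2972, 1.057 and 0.2824 TPM with the miR-150 mimic. Against the control, limma's adjusted p with miR-143 and miR-150 was 0.0387 and 0.0256 for HSD11B1 and 0.0467 and 0.0429 for KCNK6, near the threshold. TMBIM1 differed by -0.98 between the miR-126 and miR-143 mimics (-0.44 against 0.54, adjusted p = 0.000762).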

How the results depend on the processing

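Fits without the 2 libraries that favour short transcripts, with the length trend removed, with centring, quantile normalization or quality weights, with sums per Ensembl gene, and with block and estimated correlation together were chosen after the data were seen. Counts stand in the order miR-126, miR-143 and miR-150 against the control, then miR-126 against miR-143, miR-126 against miR-150 and miR-143 against miR-150, for which 702, 457, 456, 346, 537 and 301 genes passed. With the replicate number as a block they were 2331, 1775, 1694, 1515, 2599 and 1340, every gene called without the block included. For miR-143 and miR-150 against the control the numbers pair the libraries less clearly, since residual correlations were 0.04, 0.65 and 0.17, and 0.07, 0.60 and 0.07, although 11 of the 12 libraries correlated best with their own number. Without the 2 libraries they were 1835, 707, 587, 578, 696 and 262, and with the block as well 4389, 2299, 1759, 2077, 2455 and 1497. With the length trend removed they were 1508, 1084, 926, 850, 957 and 653, and with the block as well 3669, 3274, 2732, 2759, 3121 and 2486. Quality weights gave 4401, 1579, 3159, 1498, 3775 and 1297, and quantile normalization 764 for miR-143 against the control. The 6 libraries compared alone, with fewer samples for the spread, gave 1673, 266, 57, 187, 19 and 4. An absolute log2 fold change of at least 1 left 238, 147, 165, 132, 193 and 110, an adjusted p under 0.01 left 207, 139, 161, 76, 123 and 97, and tests of transcripts gave 293, 155, 191, 156, 138 and 117 genes. Dropping the filter, a pseudocount of 0.1 TPM, a filter on 6 libraries, sums per Ensembl gene and centring on the median gene kept each count within 1.5 times. Leaving out 1 library gave 214 to 472, 139 to 339, 125 to 553, 77 to 183, 117 to 717 and 127 to 353 genes. The cause of these shifts was not tested.

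Of 75 list tests, 20 passed. By contrast 0 did with an estimated correlation, 1 in fry, 2 with the block and an estimated correlation, 27 with the block, and 15 to 26 with 1 library left out. Overlaps of calls with the block were 899, 658 and 644 genes, against 217, 159 and 141. With the block, cholesterol synthesis and microRNA machinery with miR-143, and interferon-stimulated genes, miR-143 targets and fibroblast markers with miR-150, also passed, as did SLC2A1, NOTCH3 and FZD4 with miR-150 (adjusted p = 0.0135, 0.0416 and 0.0305). Between mimics it added S phase (miR-126 against miR-150) and VEGF signalling (miR-143 against miR-150). With the block and an estimated correlation these lists did not pass (adjusted p of at least 0.63 against the control, and 0.81 and 0.80 between mimics). It changed no other list test and no other call of a gene picked by the naming rule than these and those given beside the results, but more members of most lists passed with it. With the length trend removed, G2 and M phase genes also passed, toward lower values with miR-126 and higher ones with miR-150 (adjusted p = 0.017 each), as did interferon-stimulated genes between miR-126 and miR-143 (0.02) and integrins between miR-126 and miR-150 (0.032). Without the 2 libraries, S phase (0.041) and integrins (0.031) passed between miR-126 and miR-150. Among 166 calls of genes picked by the naming rule, 166 were kept with the block, 155 without the 2 libraries, 159 with the length trend removed, 157 with centring, 163 with quantile normalization, 133 without a filter and 117 with the 6 libraries alone; 91 were kept in every fit that left out 1 library and 75 were lost in at least 1. None of these calls changed its sign in these fits.

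The miR-126-3p difference (-0.19) was -0.12 for 8-mers (exact permutation p = 0.0727), -0.047 for sites in coding sequence alone (exact permutation p = 0.2455) and -0.21 to -0.16 with 1 miR-126 mimic library left out. The miR-143-3p difference (-0.16) was -0.10 for sites in coding sequence alone (exact permutation p = 0.0545) and -0.20 to -0.11 with 1 miR-143 mimic library left out. The miR-150-5p difference (-0.10), which missed the threshold, passed it for 8-mers (-0.20, exact permutation p = 0.0136). It also passed with UTR length and GC removed (-0.038, exact permutation p = 0.0091), with transcript length and level removed too (-0.044, exact permutation p = 0.0045), with the block (-0.10, exact permutation p = 0.0409) and without the 2 libraries (-0.046, exact permutation p = 0.0444), and was -0.13 to -0.03 with 1 miR-150 mimic library left out. The cause was not tested.

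Within strata of transcript length in place of 3' UTR length, also chosen after the data were seen, the odds ratio of holding a site among genes that fell was 5.24 for miR-143-3p and 2.57 for miR-150-5p. Among calls made without the 2 libraries and within strata of 3' UTR length it was 4.52 and 3.28 for genes that fell, and 0.673 and 0.665 for genes that rose (95% intervals 0.477 to 0.951 and 0.483 to 0.916).

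Not run, because TPM hold no counts, were count models, other size factors, library size alone and counts scaled by transcript length. The 3 controls were not split between comparisons, as that leaves too few on a side. What depth limits is not known, since TPM keep none.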

Other observations

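The fits with other mimics as the baseline, the scan of the control libraries and the tests of the candidate explanations were chosen after the results were seen. The predictions for base composition and for leaving out the 2 libraries that favour short transcripts were written before those tests. The patterns that they address came from these same data. Podoplanin (PDPN), a lymphatic marker, was lower with each mimic (-1.01, -1.16 and -0.63 for miR-126, miR-143 and miR-150), and keratin KRT18 was higher with the miR-143 (0.67) and miR-150 (0.90) mimics, while lists of lymphatic (adjusted p = 0.54, 0.37 and 0.42) and epithelial markers (0.77, 0.059 and 0.12) did not pass in limma's camera. In VEGF and angiopoietin signalling, APLN and ESM1 rose with each mimic, but the list did not pass (0.64, 0.5 and 0.58). PFKL, a glycolytic enzyme, rose with each mimic (0.96, 1.02 and 0.90), PGK1 and PHGDH fell with the miR-143 mimic (-0.87 and -0.79; PHGDH missed the threshold in 5 of 6 fits that left out 1 library, as KRT18 with this mimic did in 4), and the glycolysis list did not pass (0.73, 0.19 and 0.45).

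For miR-126, miR-143 and miR-150 in turn, adjusted p in camera was 0.58, 0.86 and 0.86 for NOTCH, 0.056, 0.86 and 0.29 for WNT and Norrin, 0.72, 0.95 and 0.92 for hypoxia, 0.091, 0.43 and 0.93 for S phase. It was 0.13, 0.93 and 0.22 for G2 and M phase, 0.18, 0.053 and 0.54 for cholesterol synthesis, 0.48, 0.64 and 0.11 for protein folding stress, 0.21, 0.29 and 0.54 for immediate early genes, 0.31, 0.053 and 0.23 for microRNA machinery and 0.85, 0.48 and 0.22 for fibroblast and pericyte markers. Other lists passed in at least 1 comparison. Elsewhere adjusted p was 0.35 for miR-150 targets with miR-126, 0.49 and 0.86 for miR-126 targets with miR-143 and miR-150, and 0.056 for miR-143 targets with miR-150. It was 0.86 and 0.95 for endothelial identity and 0.99 and 0.85 for p53 targets with miR-143 and miR-150, 0.55 and 0.47 for leukocyte adhesion with miR-126 and miR-150, 0.58 for integrins and 0.93 for mitochondrial mRNAs with miR-143, and 0.098 for interferon-stimulated genes with miR-150. The leukocyte list had 2 tested genes and was not tested. With the mean of the other mimics as the baseline, 496, 277 and 426 genes passed (338, 132 and 64 higher), and of the genes lower against the control 104 of 238, 74 of 204 and 146 of 307 were among them, against 90 of 464, 32 of 253 and 9 of 149 of the higher ones. Matches to bases 2 to 8 of the other arms did not pass (miR-126-5p 0.03, exact permutation p = 0.85; miR-143-5p -0.05, exact permutation p = 0.2864; miR-150-3p -0.06, exact permutation p = 0.3818). With UTR and transcript features removed, 8-mers of miR-126-5p and miR-143-5p lay at -0.018 each (exact permutation p = 0.0045 and 0.0273), against -0.142 for those of miR-150-5p, and those of miR-150-3p at 0.002 (exact permutation p = 0.8091).

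The 86 genes higher with all 3 mimics had a median log2 fold change of 0.933 without the 2 libraries that favour short transcripts, against 0.905 with them. Of these, 79 stayed past the threshold in all 3, so their calls did not rest on those libraries. All 86 genes were chosen as called with the miR-126 mimic too, a group without either library. The median over the 3 mimics could therefore hardly fall far, and it does not test those libraries as the cause. In a scan with UTR and transcript features removed, the 7-mer most strongly lower in the controls was GGTTGTG (1278 genes); chosen on odd chromosomes, it was more frequent among these genes on even chromosomes (60.98% against 10.29%, odds ratio 13.6, 95% interval 6.94 to 27.5, Fisher's exact test p = 6.3e-15). On the odd chromosomes, where it was chosen, the odds ratio was 5.59 (95% interval 2.78 to 10.9). Over all chromosomes, which include those of the choice, it was 48.84% against 10.02% (odds ratio 8.57, 95% interval 5.46 to 13.4). The shares of this 7-mer were not compared within strata of 3' UTR length. A candidate explanation is that the scrambled RNA itself lowered transcripts with that site, which matches the seed of the worm microRNA miR-67, a common negative control; its sequence is not given in the sources used here. Of the 86 genes, 44 lack the 7-mer, and for these an effect of any mimic and an effect of the scrambled RNA cannot be told apart, because it is the only baseline.

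That miR-143 mimic replicate 4 and miR-150 mimic replicate 4 favour short transcripts (correlations of -0.40 and -0.55 with length) argues against a batch shared by all libraries numbered 4, since the control and miR-126 libraries of that number had 0.24 and 0.08. It also argues against an effect of these mimics, since their replicates 2 and 3 had between -0.01 and 0.29. RNA integrity or library preparation of these libraries stays open and may be the cause, but TPM keep no coverage along transcripts that could show it.

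In the miR-126 mimic libraries, genes with GGTAC in the 3' UTR (5360), the complement of bases 3 to 7 of miR-126-3p, were lower than with the other mimics after adjustment for UTR and transcript features (-0.054, SE 0.005). Each SE in this paragraph is taken over genes and does not measure the spread between libraries. Between libraries, with the other 9 as the baseline, the score was -0.096, and -0.084 for genes with GGTAC but without GGTACG or CGGTAC (exact permutation p = 0.0045 each). Base composition is argued against by the median of 0 over the 60 orders of these bases. GGTAC was the lowest of them (next -0.044, SE 0.008). It was picked from a scan of these same libraries, so its rank was largely fixed by that choice. The next order, GTACG, is itself part of the seed match CGGTACG. Co-occurring longer seed matches are argued against too (-0.042, SE 0.005, in 4478 genes without GGTACG or CGGTAC). Those genes keep other longer sites, such as GGTACT (2153 genes, -0.088), whose part was not set apart. The 2 libraries that favour short transcripts are also argued against (-0.056 without them). The lowering was larger for ATGGTACT (316 genes, -0.174, SE 0.021). One hypothesis is that the mimic acts through pairing short of the full seed; it was found and tested on the same data.

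With 3 libraries a group there are 10 splits, too few for a share under 0.05. As many genes as in the real split were called in 1 of the 10 for miR-126 against the control (702, highest other 0), 1 for miR-143 (457, 2), 1 for miR-150 (456, 1), 1 for miR-126 against miR-143 (346, 0) and 1 for miR-126 against miR-150 (537, 1). For miR-143 against miR-150 it was 2 (301, highest other 825): the other split, which puts miR-143 mimic replicates 3 and 4 with miR-150 mimic replicate 4, follows the libraries' correlation with length and points to a structure of the samples, and with the block the real split gave 1340. For lists, adjusted within each comparison, it was 5 for miR-126 (10 lists, highest other 13), 4 for miR-143 (8, 14) and 6 for miR-150 (5, 12). List calls at the preset correlation thus do not set the real groups apart from other splits.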
